A study of Mus musculus with 6 samples.

How the data were processed

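The series measured RNA of brain endothelial cells from the cortex of mice injected with PBS or PTZ, with 3 libraries per group and no other groups. Per the labels' protocols, RNA was taken up in Trizol and libraries were made with a NEBNext kit for single cells and low input. The submitters' processing notes name CASAVA, TopHat2 2.1.1, HTSeq, edgeR and the build GRCm38, with no role or order for each. The annotation release and the strand setting of the counting are not given in the sources used here, so genes that overlap on opposite strands cannot be told apart with certainty, and the values of genes with close paralogs or pseudogenes, such as interferon-induced families, globins and ribosomal proteins, are uncertain.

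The authors deposited a matrix of raw read counts per Ensembl gene, with whole numbers for 53465 genes in 6 columns, per the file headers. It also holds 5 summary rows that name no gene (reads in no feature, ambiguous or not uniquely aligned among them), which stayed out of library sizes and tests and made up 16.1% to 22.9% of all reads per library. The authors also deposited a scaled signal per library, in which each value is the count of the matrix divided by 1 factor per library: multiplied by that factor, 100% of the values were whole within 0.01 reads. The scaled values summed to 871313 to 1125142 per library, and how the factors were chosen is not given in the sources used here. They served only as an alternative scaling. Of the gene IDs, 53274 had a symbol and 191 had none, and 53360 had coordinates in the GENCODE M21 annotation of GRCm38, from which all coordinates and gene types were taken.

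What follows was computed from the counts with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 13768 of 34777 genes with any read. Counts were scaled by TMM (factors 0.864 to 1.14) and tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest with package defaults) on a design with the group as its factor, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. SE values were derived from the fold change and its test statistic. Total counts of 11107481 to 15406967 set the counting precision, and the common dispersion of 0.221 (biological coefficient of variation 0.470) set most of the error. No 2 libraries of a group matched within sampling noise, with a chi-square per degree of freedom of 48.2 to 112.

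The groups share the replicate numbers 1, 2 and 4, which come from the sample titles. Deviations from the group means correlated at 0.167, 0.197 and 0.217 between libraries with the same number and at -0.127 to -0.062 between others, across genes, so the numbers were taken to pair the libraries by a rule of correlation over 0.1 in every pair. Deviations within a group cancel out, so positive values within pairs force negative ones between other libraries. The negative values are thus no separate evidence of pairing, and no test of the pairing itself was run. The main design has no block, and the fit with the number as a block was an alternative. The exact sign-flip tests of summed levels within these pairs were added after seeing the data.

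Before the data were examined, 21 functional gene lists and 14 lists of cell type markers were written, and 12 of the marker lists were tested because those of oligodendrocyte precursors and of choroid plexus and ependyma had under 5 tested members. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the functional lists and over the marker lists as separate families, and again with a correlation estimated per list and with fry. With an estimated correlation 0 lists passed. Members were counted over all genes and when adjusted over the list alone. Aldoa could not be matched because more than 1 ID carries the symbol.

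Genes named in the text followed a rule fixed at the same time: up to 12 per direction with the largest change among genes past the threshold, with no overlap between groups and a mean of at least 5 CPM, leaving out predicted genes, or, where under 6 pass, the 6 per direction with the smallest unadjusted p. For each list up to 4 passing members were named, or up to 2 with the smallest unadjusted p, and Pecam1, Cldn5, Slc2a1, Fos and Rpl22 were named in any case. The further members given for the immediate early and glucocorticoid lists, Ier3 and the genes of the last part of the closing section were chosen after their values were seen.

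The test was tried on simulated counts with the means and library sizes of the 13768 genes in this comparison. The genes to be changed were drawn from the 10115 with a mean of at least 5 CPM, so recovery below that level was not tested. With 100 genes changed 2-fold and 100 changed 4-fold, edgeR's quasi-likelihood test recovered 8 and 76 and called 6 unchanged genes, DESeq2 recovered 24 and 89 and called 38 unchanged genes, limma-voom 7 and 68 with 4, and the exact test 18 and 86 with 19. A simulated list of 25 genes changed 1.5-fold had a camera adjusted p of 1.06e-06, and 0 of 20 unchanged lists passed. Simulated genes were drawn independently of each other, so this does not test camera on lists whose members move together. The lists called here had estimated correlations from 0.014 (endoplasmic reticulum stress) to 0.94 (ribosomal proteins). Alternatives covered other scalings and filters, DESeq2, limma-voom, the edgeR exact test, robust dispersion, the replicate block and leaving out each library in turn. Added after seeing the data were edgeR's quasi-likelihood test with its newer option (legacy set to FALSE), the authors' scaling, and the block with DESeq2, limma-voom and the newer option.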

Results

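The libraries hold RNA of brain endothelial cells from the cortex of male mice aged 8 to 12 weeks that carried Tie2-Cre, the Ai9 reporter and Rpl22-HA. Tie2-Cre is active in endothelial cells and in part of the blood lineage, Ai9 makes cells with Cre fluoresce, and Rpl22-HA is a tagged protein of the large ribosomal subunit by which ribosomes and the messenger RNAs they translate can be isolated from cells with Cre (the RiboTag method). The series' title calls the measurement a translatome, while the step that isolated the cells or ribosomes is not given in the sources used here. The mice had been injected with phosphate-buffered saline (PBS) or with pentylenetetrazol (PTZ), a GABA-A receptor antagonist that provokes seizures, and each group held 3 libraries, numbered 1, 2 and 4. The dose of PTZ and the time between injection and collection are not given in the sources used here. Gene counts summed to 14932860, 11107481 and 13375689 in PBS libraries 1, 2 and 4 and to 12027835, 11691668 and 15406967 in the PTZ libraries, and 22683, 23823 and 22686 genes in PBS and 25048, 25620 and 23867 in PTZ had at least 1 read, so that all PTZ libraries lay above all PBS libraries (exact 2-sided permutation p = 0.1, the smallest possible). Nothing in the labels says that the libraries of a group came from separate animals. The p-values of single genes and of library permutations thus measure only the spread between these libraries, which may be technical. Camera with the preset correlation compares a list's members with the other genes, treated as nearly independent. Its p-values therefore rest mainly on the spread over genes and do not measure the spread between libraries. Levels are CPM (reads of a gene scaled to a common library total) after TMM scaling, as mean ± SD over n = 3 libraries per group, and log2 fold changes are PTZ against PBS with their standard error (SE). The endothelial gene Pecam1 stood at 642 ± 76.6 CPM in PTZ and 553 ± 69.6 CPM in PBS. Rpl22, the tagged gene, stood at 77.9 ± 33.0 CPM and 76.0 ± 16.5 CPM, a log2 fold change of 0.04 (SE 0.33) that turned negative under several settings, the authors' own scaling among them (-0.03).

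The comparison of PTZ with PBS asks how the RNA of brain endothelial cells differs after an acute convulsant. Predicted genes aside, genes higher in PTZ with a mean of at least 5 CPM were ranked by p-value. The first encode a feedback inhibitor of growth factor signalling, an enzyme of retinoic acid synthesis, a chemokine and a cytoskeletal regulator. For each of them all 3 PTZ libraries lay above all 3 PBS libraries. Errfi1 (ENSMUSG00000028967, protein coding, chromosome 4, 150853919 to 150868892 on the plus strand, GRCm38), an inhibitor of the epidermal growth factor receptor, stood at 149 ± 10.6 CPM in PTZ and 19.7 ± 12.9 CPM in PBS, a log2 fold change of 2.93 (SE 0.40). Aldh1a2 (ENSMUSG00000013584, protein coding, chromosome 9, 71215789 to 71296243, plus strand), a retinaldehyde dehydrogenase, stood at 18.2 ± 9.33 CPM and 1.42 ± 0.486 CPM, a log2 fold change of 3.67 (SE 0.57). Ccl2 (ENSMUSG00000035385, protein coding, chromosome 11, 82035571 to 82037453, plus strand), a chemokine that attracts monocytes, stood at 15.4 ± 8.35 CPM and 0.917 ± 0.348 CPM, a log2 fold change of 4.05 (SE 0.64). Cdc42ep3 (ENSMUSG00000036533, protein coding, chromosome 17, 79333727 to 79355091, minus strand), an effector of the small GTPase Cdc42, stood at 114 ± 18.1 CPM and 40.6 ± 7.99 CPM, a log2 fold change of 1.5 (SE 0.24). Tmcc3 (1.36, SE 0.24) and Tiparp (1.93, SE 0.36), a mono-ADP-ribosyltransferase, completed the group. Which cells these reads came from was not tested, and markers of mural cells and fibroblasts were also higher in PTZ, as described below.

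Among genes lower in PTZ, ranked by p-value with the same minimum of 5 CPM, an enzyme that modifies heparan sulfate came first. Genes of RNA handling, immune restraint and coenzyme A turnover followed, again with no overlap between the groups. Hs3st1 (ENSMUSG00000051022, protein coding, chromosome 5, 39613935 to 39755475, minus strand), a heparan sulfate sulfotransferase, stood at 80.6 ± 16.0 CPM in PTZ and 188 ± 25.2 CPM in PBS, a log2 fold change of -1.22 (SE 0.23). Gpatch11 (ENSMUSG00000050668, protein coding, chromosome 17, 78835567 to 78848308, plus strand) stood at 48.8 ± 4.70 CPM and 103 ± 15.1 CPM, a log2 fold change of -1.07 (SE 0.21). Lsm8 (ENSMUSG00000044155, protein coding, chromosome 6, 18848579 to 18855751, plus strand), part of a nuclear ring that binds a spliceosomal RNA, stood at 50.9 ± 4.66 CPM and 97.6 ± 0.954 CPM, a log2 fold change of -0.94 (SE 0.20). Tnfaip8l2, a negative regulator of immune signalling, had a log2 fold change of -1.33 (SE 0.29), the chemokine Ccl12 -1.88 (SE 0.41) and Nudt7, a peroxisomal coenzyme A hydrolase, -1.55 (SE 0.35). The cells of origin were not tested here either, and markers of microglia were also lower in PTZ.

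No single gene passed the threshold in the main test. In edgeR's quasi-likelihood test 0 of 13768 genes were higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.283, shared by Errfi1, Aldh1a2, Ccl2 and Cdc42ep3. Members of lists that passed in edgeR are counted in this test. At an unadjusted p under 0.05 stood 993 genes, 528 higher and 465 lower, where chance gives 688 on average, and 14.3% of the genes tested had groups that did not overlap, where chance gives 10% on average. Genes vary together, and other splits of the libraries that keep a pair of replicate numbers together gave up to 968 genes at that p. The others that part all pairs gave 218, 228 and 393, and they are too few for a share under 0.25. Other tools called some genes at the same threshold: DESeq2 called 57 higher and 42 lower, the edgeR exact test 37 and 20, and limma-voom 1 and 0, Errfi1. Leaving out the low-count filter gave 77 higher and 44 lower in edgeR. With the replicate number as a block the main test still called 0 and 0. The block gave 113 and 81 in DESeq2, 11 and 2 in limma-voom and 11 and 1 with edgeR's newer option, fits added after seeing the data. Without PBS replicate 2 the main test called 8 genes higher and 0 lower. The biological coefficient of variation was 0.470, and on simulated counts of this design the main test recovered 8 of 100 genes changed 2-fold and 76 of 100 changed 4-fold. The changed genes all had a mean of at least 5 CPM.

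**Figure D1:**
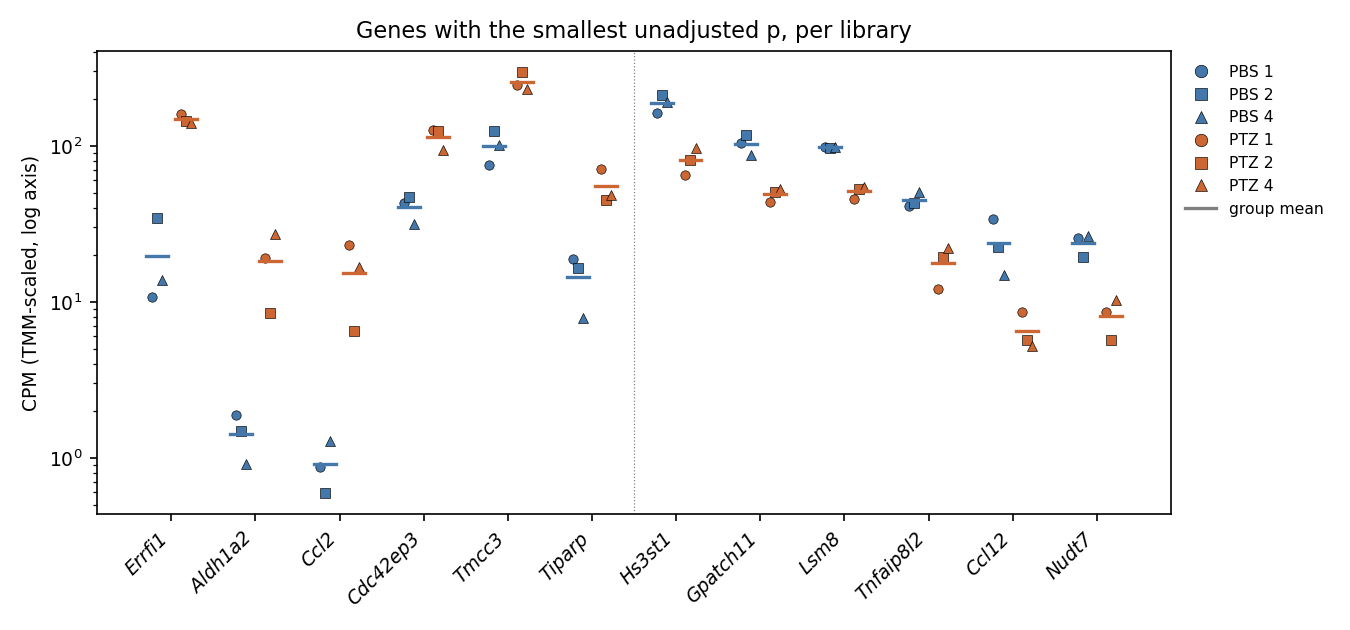
TMM-scaled CPM per library (log axis) of the 6 genes with the smallest unadjusted p in each direction among those with a mean of at least 5 CPM, left of the dotted line higher and right of it lower in PTZ. Points are libraries, shapes replicate numbers and bars group means; Errfi1 lay at 141 to 161 CPM in the PTZ libraries and at 10.7 to 34.5 CPM in the PBS libraries, and no gene shown passed adjustment over all genes in the main test.

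Immediate early transcription factors and regulators, which are transcribed within minutes of a stimulus, rose as a list in PTZ. Of 37 tested members 29 had a positive log2 fold change, the median was 0.55, and 13 were higher and 1 lower at an unadjusted p under 0.05. No member passed over all genes tested and 8 passed in edgeR when adjusted over the list alone, all higher: Csrnp1, Nr4a3, Dusp1, Trib1, Fosb, Jun, Nr4a2 and Fosl2. Csrnp1, a nuclear transcriptional regulator, stood at 114 ± 6.23 CPM in PTZ and 35.99 ± 17.4 CPM in PBS (log2 fold change 1.67, SE 0.31). The nuclear receptor Nr4a3 stood at 18.0 ± 7.33 CPM and 3.33 ± 1.04 CPM (2.43, SE 0.48), and Dusp1, a phosphatase of MAP kinases, at 188 ± 39.1 CPM and 68.5 ± 28.9 CPM (1.46, SE 0.31). Fos stood at 69.1 ± 17.9 CPM and 29.0 ± 22.7 CPM (1.26, SE 0.51), with overlapping libraries. Ier3 was the member with a negative value at that unadjusted threshold (-1.30, SE 0.57), and it passed over all genes in 4 of the 21 alternatives. The list's camera adjusted p in limma was 2.73e-11, and adjusted p = 0.416 with an estimated correlation. The summed level of the list was 2595, 5081 and 2891 CPM in PBS libraries 1, 2 and 4 and 4671, 4490 and 4937 CPM in PTZ. PBS replicate 2 was the highest of all 6 libraries and the groups overlapped (exact 2-sided permutation p = 0.4). Within pairs of equal replicate number it rose in pairs 1 and 4 and fell in pair 2 (exact 2-sided sign-flip p = 0.5, where 0.25 is the smallest possible). The 8 members became 14 with the replicate number as a block, and 4, 18, 2 and 5 without PBS replicates 1, 2 and 4 and without PTZ replicate 4.

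Genes known to respond to glucocorticoids also rose as a list. Of 23 tested members 20 had a positive log2 fold change, the median was 0.71, and 9 had all PTZ libraries above all PBS libraries. No member passed over all genes and 5 passed in edgeR when adjusted over the list alone: Errfi1, Ddit4, Arl4d, Dusp1 and Klf9. Ddit4, an inhibitor of mTOR signalling, stood at 103 ± 45.4 CPM in PTZ and 29.1 ± 8.40 CPM in PBS (1.83, SE 0.36), the small GTPase gene Arl4d at 158 ± 45.5 CPM and 64.2 ± 14.3 CPM (1.30, SE 0.27), and the transcription factor Klf9 at 369 ± 27.6 CPM and 230 ± 10.2 CPM (0.68, SE 0.21). Dusp1 belongs to both lists. The camera adjusted p in limma was 5.20e-12, and adjusted p = 0.277 with an estimated correlation. Limma's fry gave an adjusted p of 0.113 for a shift in 1 direction and 0.0397 for change in either direction. The summed level was 7686, 12195 and 7120 CPM in PBS libraries 1, 2 and 4 and 9428, 21473 and 10086 CPM in PTZ. It rose within all 3 pairs of equal replicate number (exact 2-sided sign-flip p = 0.25, the smallest possible). Across pairs PBS replicate 2 lay above PTZ replicates 1 and 4 (exact 2-sided permutation p = 0.4). Lcn2, a member whose level varied widely between libraries (given in the closing section), made up a large part of the sum in PTZ replicate 2. The order of the libraries by this sum thus rests in part on that gene. The 5 members became 14 with the replicate block and 9 without PBS replicate 2.

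Genes of the vascular basement membrane and its receptors rose together. Of 29 tested members 26 had a positive log2 fold change, with a median of 0.54, 7 were higher and 0 lower at an unadjusted p under 0.05, and 0 passed in edgeR either over all genes or adjusted over the list alone. Col4a2 stood at 208 ± 35.1 CPM in PTZ and 115 ± 20.05 CPM in PBS (0.86, SE 0.23) and its neighbour Col4a1, the other main chain of collagen IV in vessels, at 212 ± 10.5 CPM and 129 ± 30.0 CPM (0.72, SE 0.23). The camera adjusted p in limma was 6.72e-07, and adjusted p = 0.379 with an estimated correlation. Markers of pericytes, smooth muscle and fibroblasts, which also make these proteins, had higher fold changes in the same libraries, with medians of 1.18 and 1.09. The summed level of the basement membrane list was 6572, 9446 and 9350 CPM in PBS libraries 1, 2 and 4. In the PTZ libraries it was 7125, 10384 and 9859 CPM, so the groups overlapped (exact 2-sided permutation p = 0.5). It rose within all 3 pairs of equal replicate number (exact 2-sided sign-flip p = 0.25, the smallest possible).

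Genes of the endoplasmic reticulum stress and integrated stress response rose as a list by a smaller amount. Of 28 tested members 22 had a positive log2 fold change (median 0.22), 2 were higher at an unadjusted p under 0.05 and 0 passed in edgeR, over all genes or adjusted over the list alone. Herpud1, a factor in degradation of misfolded proteins, stood at 367 ± 118 CPM in PTZ and 184 ± 26.7 CPM in PBS (0.99, SE 0.27), and the transcription factor Atf4 at 191 ± 15.4 CPM and 126 ± 6.43 CPM (0.60, SE 0.19). The camera adjusted p in limma was 0.0407, and adjusted p = 0.416 with an estimated correlation. The call was lost without PBS replicate 1 (camera adjusted p = 0.270), PBS replicate 4 (0.112) or PTZ replicate 4 (0.210). The summed level was 2791, 3525 and 3153 CPM in PBS libraries 1, 2 and 4 and 3935, 3765 and 3655 CPM in PTZ. All PTZ libraries thus lay above all PBS libraries (exact 2-sided permutation p = 0.1, the smallest possible).

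Nuclear genes of oxidative phosphorylation and genes of cytosolic ribosomal proteins fell as lists, and mitochondrially encoded messenger RNAs rose as a list, all by small amounts and with no member passing in edgeR over all genes or over its list alone. Of 75 nuclear oxidative phosphorylation genes 61 had a negative log2 fold change (median -0.24), among them Sdhd, a subunit of succinate dehydrogenase (23.5 ± 4.18 CPM in PTZ, 45.3 ± 9.94 CPM in PBS, log2 fold change -0.95, SE 0.27), and Ndufs3 of complex I (-0.54, SE 0.24). Of 79 ribosomal protein genes 65 had a negative value (median -0.11), with Rplp2 at -0.67 (SE 0.33). All 11 mitochondrially encoded messenger RNAs had a positive value (median 0.39), with mt-Co1 at 642 ± 177 CPM and 408 ± 334 CPM (0.66, SE 0.54) and mt-Nd4 at 0.71 (SE 0.65). Camera adjusted p in limma was 1.21e-04 for the nuclear genes, 0.0072 for the ribosomal proteins and 0.0407 for the mitochondrial messenger RNAs, and for each of these lists adjusted p = 0.856 with an estimated correlation. The summed levels of these lists overlapped between the groups (exact 2-sided permutation p = 0.5, 0.9 and 0.5 in that order). For the nuclear genes PTZ replicate 2 was the highest of all 6 libraries (34929 CPM) and PTZ replicate 1 the lowest (18275 CPM). The same held for the ribosomal proteins (54325 and 16268.5 CPM). Without PTZ replicate 1 the fall of the nuclear genes was lost (0.250) and the ribosomal list turned upward without passing (0.138). The ribosomal call was also lost without PBS replicate 2 (0.776) or PTZ replicate 4 (0.429), and the mitochondrial call without PBS replicate 1 (0.924), PBS replicate 2 (0.255) or PTZ replicate 4 (0.522). PTZ replicate 1 also had the highest share of reads outside annotated features, 9.34% against 2.99% to 5.19% in the other libraries.

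**Figure D2:**
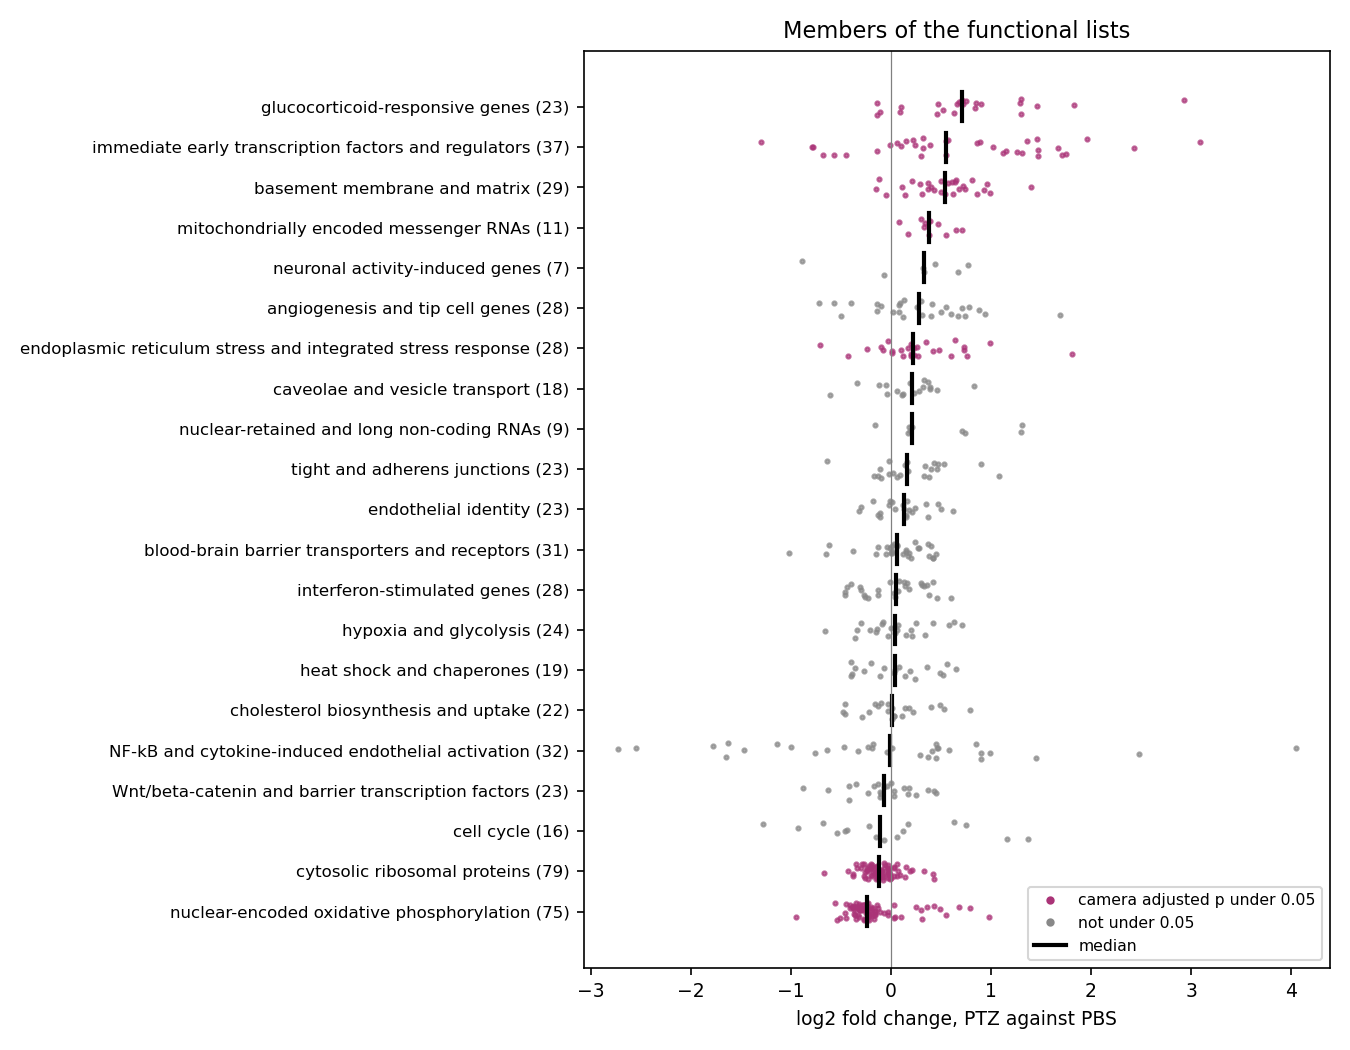
Log2 fold change, PTZ against PBS, of each tested member of the 21 functional lists, with the number of members in brackets and the median as a black bar. Coloured lists had a camera adjusted p under 0.05 with the preset correlation; medians ran from -0.24 for oxidative phosphorylation to 0.71 for glucocorticoid-responsive genes, and none of the lists passed with an estimated correlation.

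Genes of the blood-brain barrier gave no call in the main test. Tight and adherens junction genes had a median of 0.16 over 23 members, 16 of them positive and 0 passing in edgeR, with a camera adjusted p of 0.075. With the replicate block the camera adjusted p was 0.0409, so the list passed there. In the main design its adjusted p = 0.457 with an estimated correlation. Gja4, a connexin of arterial endothelium, stood at 370 ± 125 CPM in PTZ and 175 ± 94.0 CPM in PBS (1.08, SE 0.42), and the junction protein gene Cgnl1 at 195 ± 47.3 CPM and 135 ± 14.9 CPM (0.53, SE 0.23). Cldn5, the main claudin of the barrier, stood at 910 ± 547 CPM and 813 ± 386 CPM (0.16, SE 0.46). Barrier transporters and receptors had a median of 0.06 over 31 members (camera adjusted p = 0.536). In that list the transferrin receptor gene Tfrc stood at 29.1 ± 10.5 CPM in PTZ and 58.7 ± 8.85 CPM in PBS (-1.02, SE 0.30), the iron exporter gene Slc40a1 at 47.2 ± 17.9 CPM and 73.9 ± 22.7 CPM (-0.64, SE 0.31), and the glucose transporter gene Slc2a1 at 5474 ± 2642 CPM and 4924 ± 1251 CPM (0.15, SE 0.41). Cldn5 and Slc2a1 turned negative without PTZ replicate 2 (-0.46 and -0.36), Cldn5 also without PBS replicate 4 (-0.12) and Slc2a1 without PBS replicate 1 (-0.02).

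The other lists of vessel biology also gave no call by camera. Genes of caveolae and vesicle transport had a median of 0.21 over 18 members (camera adjusted p = 0.183), with Cav2 at -0.60 (SE 0.31) and the lipid transporter gene Mfsd2a at 0.37 (SE 0.22). Limma's fry, which does not compare a list with other genes, gave that list an adjusted p of 0.0459. Wnt and barrier transcription factor genes had a median of -0.07 over 23 members (camera adjusted p = 0.536), with Sox7 at 33.6 ± 6.59 CPM in PTZ and 52.1 ± 12.7 CPM in PBS (-0.63, SE 0.27) and Lrp6 at 0.45 (SE 0.24). Endothelial identity genes had a median of 0.13 over 23 members (camera adjusted p = 0.426), with Cdh5 at 0.48 (SE 0.23) and Erg at 0.62 (SE 0.33), and angiogenesis and tip cell genes a median of 0.28 over 28 members (0.116), with Thbs1 at 1.69 (SE 0.60) and Notch4 at 0.79 (SE 0.31). Identity genes passed without PTZ replicate 1 (0.0442) and angiogenesis genes without PBS replicate 2 (0.00996). The summed level of the angiogenesis list was 4232 to 4645 CPM in the PTZ libraries and 2951 to 3949 CPM in PBS. Its groups thus did not overlap (exact 2-sided permutation p = 0.1, the smallest possible).

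Inflammatory and metabolic lists gave no call in the main test either. The NF-kB and cytokine list held 16 positive and 16 negative members, with a median of -0.01 and an upward camera statistic that did not pass (adjusted p = 0.484). In it 2 members, Ccl2 and Ccl7, passed in edgeR adjusted over the list alone and 0 over all genes. Ccl7, a chemokine of the same cluster, stood at 46.5 ± 33.8 CPM in PTZ and 8.29 ± 4.30 CPM in PBS (2.48, SE 0.58). The list passed upward without PBS replicate 2 (3.85e-06) or PTZ replicate 4 (0.0197), had a downward statistic that did not pass without PBS replicate 1, PBS replicate 4 or PTZ replicate 2 (0.873, 0.255 and 0.562), and 4 of its members passed over the list alone with the replicate block. The 2 members became 7 without PBS replicate 2, 1 without PBS replicate 1 or PTZ replicate 1, and 0 in limma-voom. Interferon-stimulated genes had a median of 0.06 over 28 members with a downward statistic (camera adjusted p = 0.872), and Oas1a, whose reads can be shared with close paralogs, stood at -0.43 (SE 0.21). Hypoxia and glycolysis genes had a median of 0.04 over 24 members (0.687), with Ndrg1 at 0.63 (SE 0.25) and Pfkfb3 at 0.71 (SE 0.28). Heat shock genes (median 0.04 over 19 members, camera adjusted p = 0.872, downward statistic), cholesterol genes (0.01 over 22, 0.9999, downward) and cell cycle genes (-0.11 over 16, 0.487) did not pass. Nor did neuronal activity-induced genes (0.33 over 7, 0.484) or nuclear-retained RNAs (0.21 over 9, 0.111). Nuclear-retained RNAs passed without PTZ replicate 4 (0.00356), and Neat1 of that list stood at 146 CPM in PTZ replicate 1 against 17.5 to 41.5 CPM in the other libraries. The medians of the NF-kB, interferon, heat shock and cholesterol lists have signs opposite to their camera statistics and so do their means of -0.05, 0.02, 0.06 and 0.03.

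Markers of mural cells and fibroblasts were higher in the PTZ libraries and markers of microglia lower. The pericyte and smooth muscle list rose, with all 15 tested members positive and a median log2 fold change of 1.18. Higd1b, a pericyte gene, stood at 60.4 ± 18.1 CPM in PTZ and 21.7 ± 6.45 CPM in PBS (1.48, SE 0.32) and was the 1 member that passed in edgeR adjusted over the list alone (4 with the replicate block). Cnn1, a smooth muscle protein gene, stood at 12.2 ± 8.80 CPM and 2.90 ± 1.37 CPM (2.07, SE 0.67). The fibroblast and meninges list rose, with all 10 tested members positive (median 1.09), and 2 members passed over the list alone, Col1a2 at 42.2 ± 19.9 CPM and 13.2 ± 2.54 CPM (1.69, SE 0.40) and Col1a1 at 20.95 ± 15.4 CPM and 4.10 ± 2.49 CPM (2.36, SE 0.65). The microglia list fell, with 0 of 15 members positive (median -0.44) and 0 passing over the list alone, Selplg standing at 74.3 ± 28.4 CPM and 146 ± 46.3 CPM (-0.98, SE 0.31) and Aif1 at 144 ± 25.2 CPM and 225 ± 13.3 CPM (-0.65, SE 0.21). Camera adjusted p in limma was 1.09e-07, 1.32e-04 and 1.33e-06 for these lists, and for each adjusted p = 0.439 with an estimated correlation. The fibroblast call was lost without PTZ replicate 4 (0.0895). The 1 mural member that passed over its list became 0 without PBS replicate 1 or PTZ replicate 1, 3 without PBS replicate 4 and 8 without PTZ replicate 2. The 2 fibroblast members became 0 without PBS replicate 1 or PTZ replicate 4, 1 without PBS replicate 2, 3 without PTZ replicate 1 and 5 without PTZ replicate 2. The summed level of the mural markers was 1934, 725 and 1868 CPM in PTZ libraries 1, 2 and 4 and 373, 747 and 1023 CPM in PBS, so the groups overlapped (exact 2-sided permutation p = 0.3, where 0.1 is the smallest possible). It rose in pairs 1 and 4 and fell in pair 2 (exact 2-sided sign-flip p = 0.5). The summed level of the fibroblast markers was 1516, 3024 and 4484 CPM in PTZ and 1966, 1953 and 1895 CPM in PBS, so PTZ replicate 1 lay below all PBS libraries (exact 2-sided permutation p = 0.4). It fell in pair 1 and rose in pairs 2 and 4 (exact 2-sided sign-flip p = 0.5). Col1a2 and Col1a1 made up little of this sum. In PTZ replicate 1 they stood at 52.6 and 18.8 CPM, above all PBS libraries (at most 15.9 and 6.95 CPM). The summed level of the microglia markers was 2511, 3267 and 3704 CPM in PTZ and 4654, 3637 and 4610 CPM in PBS, so the groups overlapped (exact 2-sided permutation p = 0.2). Within pairs the microglia level fell in all 3 (exact 2-sided sign-flip p = 0.25, the smallest possible).

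Of the other marker lists, camera called arterial endothelial genes higher, and leukocyte and platelet genes lower. Arterial genes had a median of 0.22 over 15 members (camera adjusted p = 0.0368, and adjusted p = 0.512 with an estimated correlation), with Gja4 above and Sema3g at 0.61 (SE 0.29). Perivascular macrophage and leukocyte genes had a median of -0.19 over 18 members (0.0368, and adjusted p = 0.439 with an estimated correlation), with Coro1a, a leukocyte actin regulator, at 35.7 ± 13.2 CPM in PTZ and 74.6 ± 15.9 CPM in PBS (-1.07, SE 0.32) and the B cell gene Ms4a1 at -2.52 (SE 0.88). Platelet genes had a median of -0.47 over 7 members (0.0356, and adjusted p = 0.439 with an estimated correlation), with Itga2b at -0.69 (SE 0.37) and Ppbp at -0.45 (SE 0.26). No member of these lists passed in edgeR adjusted over its list alone. The summed platelet level was 441, 434 and 317 CPM in PBS libraries 1, 2 and 4 and 343, 465 and 345 CPM in PTZ. It was thus higher in PTZ in 2 of 3 pairs of equal replicate number. The summed arterial level was higher in 2 pairs (exact 2-sided permutation p = 0.8) and the leukocyte level in 1 (exact 2-sided permutation p = 0.4). The arterial call was lost without PBS replicate 1, PTZ replicate 2 or PTZ replicate 4 (0.514, 0.333 and 0.124), the leukocyte call without PBS replicate 1, PTZ replicate 1 or PTZ replicate 4 (0.315, 0.0678 and 0.147), and the platelet call without PBS replicate 1, PBS replicate 2, PTZ replicate 2 or PTZ replicate 4 (0.0792, 0.215, 0.0666 and 0.218). No call was made for venous genes (camera adjusted p = 0.737, with Il1r1 at 0.45, SE 0.22, and Slc38a5 at -0.38, SE 0.26) or capillary genes (0.705, with Tfrc at -1.02 as above and Rgcc at 1.02, SE 0.32). Neuron genes (0.705), with Snap25 at 2.31 ± 1.27 CPM in PTZ and 0.586 ± 0.196 CPM in PBS and Thy1 at 1.39 (SE 0.97), and oligodendrocyte genes (0.705), with Cldn11 at -0.91 (SE 0.34), did not pass. Astrocyte genes (0.384, with Fgfr3 at 0.72, SE 0.48) passed without PTZ replicate 1 (7.28e-04), and erythroid genes (0.288, with Alas2 at -0.33, SE 0.24) without PTZ replicate 2 (0.0115).

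**Figure D3:**
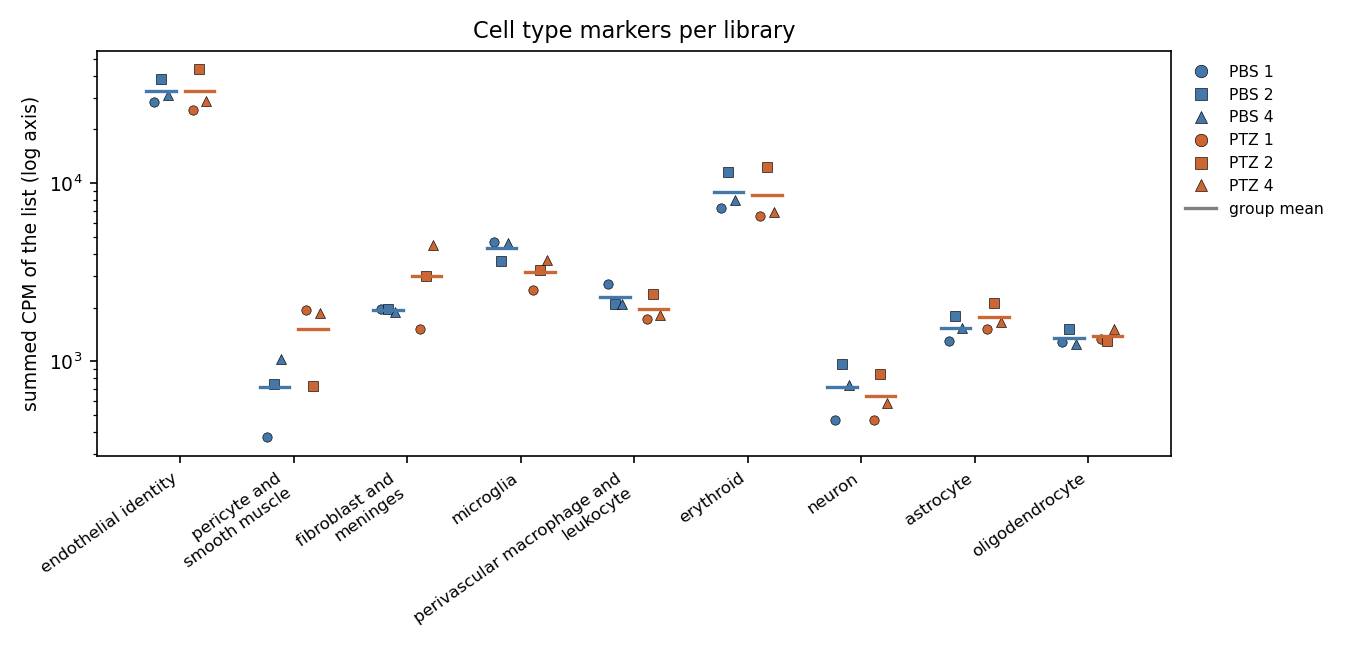
Summed TMM-scaled CPM (log axis) of the endothelial identity list and 8 marker lists in each library, with points for libraries, shapes for replicate numbers and bars for group means. Mural markers summed to 373 to 1023 CPM in the PBS libraries and to 725 to 1934 CPM in the PTZ libraries, and the groups overlapped.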

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

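Of the tests in this part, those of neuron RNA, of a lower endothelial share, of mural sampling and of PTZ replicate 1 were chosen only after the result was seen.

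Reads in no annotated feature, which the comparisons do not use, made up 9.34% of all reads in PTZ replicate 1, above the highest PBS library (5.19%).

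The immediate early and glucocorticoid-responsive lists were higher in PTZ, with a median log2 fold change of 0.66 over their 59 members together. The real split of the libraries gave a mean absolute list z (from the members' p-values, averaged over the lists) of 1.41 and the highest of the other 9 splits 1.10, from a split that keeps a pair of replicate numbers together, while the 3 others that part all pairs gave 0.33, 0.74 and 0.30, and 10 splits are too few for a share under 0.05 (1 of 10 was as large). The splits that part all pairs are by themselves too few for a share under 0.25. With each library's mural and fibroblast marker level as a covariate the median was 0.72 (95% bootstrap interval over genes 0.40 to 0.99), so it did not fall. That interval leaves out the spread between libraries, so the fit cannot decide whether mural RNA is a cause. A larger share of neuron RNA stays open: the neuron list's median lay below that of the lists (difference -0.63, 95% bootstrap interval over genes -1.01 to -0.26), but by less than the SD of 0.71 over its members, of which 8 were positive and 7 negative, and single values go both ways. The summed neuron level was 468, 961 and 731 CPM in PBS libraries 1, 2 and 4 and 468, 848 and 586 CPM in PTZ, higher in 0 of 3 pairs, though Stmn2, Nefm and Uchl1 make up most of it and their high baseline would hide a small share. Snap25, near the floor, was higher in all PTZ libraries than in all PBS libraries. An unchanged small share of neurons whose own activity genes rose was not tested and stays open: in PBS libraries 1, 2 and 4 and then PTZ libraries 1, 2 and 4, Npas4 had 0, 0, 2, 3, 1 and 8 reads and Arc 1, 16, 1, 22, 0 and 0, so that single libraries carried most of them, while Fos had 775 to 1084 reads in the PTZ libraries. A response of endothelial cells to PTZ, to seizures or to stress hormones, which the design does not separate, also stays open and was not tested.

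Mural and fibroblast markers were higher in PTZ. A lower share of endothelial RNA would raise all other cell types alike only if their RNA entered the libraries in the same way. The microglia list's median lay far below that of the mural list (difference -1.62, 95% bootstrap interval over genes -1.97 to -1.26). Tie2-Cre is also active in part of the blood lineage, and whether microglia carried Cre was not tested. The interval leaves out the spread between libraries. The comparison thus cannot decide whether the endothelial share was lower. Uneven sampling of mural cells between libraries stays open, since the summed mural level overlapped between the groups (exact 2-sided permutation p = 0.3): PTZ replicate 2, at 725 CPM, lay below PBS replicates 2 and 4. The summed fibroblast level overlapped as well (exact 2-sided permutation p = 0.4), with PTZ replicate 1, at 1516 CPM, below all PBS libraries (1895 to 1966 CPM). Col1a2 and Col1a1, small parts of that sum, went the other way in PTZ replicate 1. They stood at 52.6 and 18.8 CPM there and at most at 15.9 and 6.95 CPM in PBS. The sum therefore does not show that PTZ replicate 1 held the least fibroblast RNA. A change within mural cells, or a drop in microglial RNA beside it, was not tested.

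Oxidative phosphorylation and ribosomal protein genes were lower in PTZ, with a median of -0.16 over 154 genes in edgeR and -0.30 on mean log2 CPM. After each library's trend with transcript length and GC content was removed, the latter was -0.18 (95% bootstrap interval over genes -0.19 to -0.15). Part of the difference in these libraries thus remained without the length and GC trends. The interval resamples genes that move together and leaves out the spread between libraries. It cannot show that the rest lies beyond that spread. Without PTZ replicate 1 the edgeR median was 0.081 (0.02 to 0.13), with -0.07 for oxidative phosphorylation and 0.20 for ribosomal proteins, so the pattern may rest on that library. Whether that library differs for technical reasons or in its response to PTZ was not tested.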

How the results depend on the processing

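Of the 84 genes with fold changes named in the text 78 kept their direction under all 21 alternatives, and 47 passed under some alternative. Many were named for a small p, which by itself favours a kept direction. Genes higher and lower numbered 0 and 0 in the main test, and also with RLE, library-size, upper-quartile and authors' scaling, the stricter filter, robust dispersion and the newer edgeR option. A fold threshold, planned as well, could give only 0 and 0 and tests nothing here. They numbered 77 and 44 with no filter, 57 and 42 in DESeq2, 37 and 20 in the exact test and 1 and 0 in limma-voom. Leaving out each library gave 0 to 8 higher, the 8 without PBS replicate 2, and 0 lower. The tools also differed in the simulation, where DESeq2 called 38 unchanged genes and the quasi-likelihood test 6. The cause of the other differences was not tested.

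The replicate block left the quasi-likelihood counts at 0 and 0 (smallest adjusted p 0.0802). The block gave 113 and 81 in DESeq2, 11 and 2 in limma-voom and 11 and 1 with the newer edgeR option, all added after seeing the data. Members passing over the list alone became 14 for immediate early and 14 for glucocorticoid-responsive genes, from 8 and 5. Among set tests the block changed the junction list, from 0.075 to 0.0409, and no other call.

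With an estimated correlation 0 functional and 0 marker lists passed, from 7 and 6, and with fry 1 and 0. Leaving out each library gave 5 to 7 functional and 2 to 6 marker lists, lowest without PTZ replicate 4 (2) and PBS replicate 1 (3), 2 to 18 immediate early members and 4 to 9 glucocorticoid-responsive members. The ribosomal list's adjusted p ran from 3.89e-35 to 0.776 and turned upward without PTZ replicate 1 (0.138).

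Directions turned for these genes, none of which passed in the main test. Rpl22 stood at -0.0097 with no filter, -0.053 in limma-voom, -0.040 with the replicate block, -0.033 with the authors' scaling, and with the block -0.069 in DESeq2, -0.022 in limma-voom and -0.032 with the newer edgeR option. Leaving out each library gave -0.29 to 0.34 for Rpl22, -0.46 to 0.58 for Cldn5, -0.36 to 0.35 for Slc2a1, -0.15 to 1.06 for Fgfr3, -0.021 to 1.79 for mt-Nd4 and -1.26 to 1.38 for Lcn2. Depth and spread limit what could be seen: the main test recovered 8 of 100 simulated 2-fold changes in genes with a mean of at least 5 CPM.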

Other observations

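Genes in this part were chosen after their values were seen, and the tests of splits were planned before.

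Txnip, Depp1 and Apold1 lay higher in all 3 PTZ libraries than in all 3 PBS libraries. Txnip, a glucose-sensitive inhibitor of thioredoxin, stood at 1398 ± 71.9 CPM in PTZ and 638 ± 117 CPM in PBS (n = 3, log2 fold change 1.13, SE 0.26). Depp1, a target of FOXO transcription factors, stood at 2696 ± 669 CPM and 1029 ± 455 CPM (1.39, SE 0.39). Apold1, an endothelial early response gene, stood at 786 ± 127 CPM and 213 ± 178 CPM (1.88, SE 0.49). Lower in all 3 PTZ libraries were Id3, an inhibitor of DNA-binding transcription factors (1483 ± 384 CPM and 3000 ± 282 CPM, -1.02, SE 0.31), Zfp36l1, which promotes decay of messenger RNAs (102 ± 46.7 CPM and 482 ± 380 CPM, -2.23, SE 0.53), and Ptgs2, the inducible cyclooxygenase (10.1 ± 2.93 CPM and 31.1 ± 21.3 CPM, -1.63, SE 0.47). None of these passed adjustment over all genes in the main test. All kept their direction under the 21 alternatives, which is nearly certain for genes whose groups do not overlap. Apold1 passed in 7 of them, Txnip in 5, Depp1 in 4, Zfp36l1 in 3, and Id3 and Ptgs2 in 2 each.

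Some inflammatory genes varied widely between libraries of a group. The iron-binding secreted protein gene Lcn2 stood at 2063, 2880 and 373 CPM in PBS libraries 1, 2 and 4 and at 1174, 8053 and 354 CPM in PTZ, and Serpina3n at 209, 249 and 47.0 CPM and at 332, 1591 and 27.1 CPM, so library 4 was lowest in both groups.

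Elane, neutrophil elastase, stood at 13.4, 3.06 and 2.80 CPM in PBS libraries 1, 2 and 4 and had 0 reads in all PTZ libraries. Camp, another gene of neutrophil granules, stood at 64.6, 10.96 and 7.71 CPM in PBS and at 3.29, 7.84 and 1.57 CPM in PTZ, so its groups overlapped. Elane was the 1 gene at 0 in every library of a group and at 1 CPM or more in every library of the other. Other splits gave up to 2 such genes, and 7 of the 10 splits gave as many as the real one, so dropout at random in low-input libraries may account for it. With 0 reads in every PTZ library, the log2 fold change of Elane could only be negative in the 21 alternatives (-9.83 to -7.03). Its direction therefore says nothing about chance. Elane passed in 4 of them: no filter (adjusted p = 2.62e-07, the lowest), DESeq2, the exact test, and DESeq2 with the replicate block, which was added after seeing the data. It did not pass in the main test (0.392), and whether it differs beyond chance stays open.

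For the count of genes at an unadjusted p under 0.05 the real split gave 993 and the highest other split 968, with 1 of 10 splits as large as the real one, and 10 splits are too few for a share under 0.05. The 3 other splits that part all the pairs of replicate numbers, as the real split does, gave 218, 228 and 393. If the numbers pair the libraries, only these can be set against the real split, and they allow no share under 0.25. The pairing was itself inferred from these data. The splits that keep a pair together gave up to 968.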
